A study of Homo sapiens with 4 samples.

How the data were processed

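Micro-C contacts were compared between 2 control libraries and 2 TDP-43 knockdown libraries of SH-SY5Y cells. Per the labels, the shRNA lines were selected with puromycin at 2 µg/mL for 2 weeks and kept at 1 µg/mL. The library titles end in "merged", and what was merged is not stated. The submitters' processing notes name HiC-Pro and the hg38 build, with no versions. The deposited table gives, for 89239 pairs of 50 kb bins, raw contact counts per library, so the unit of these columns is the count. Per the file headers it also gives the authors' fold change and mean abundance, both on the log2 scale, an F statistic, and a p-value with its adjusted value. Those column names are the ones edgeR's quasi-likelihood test writes, which no header states in words. The authors' adjusted value equals the Benjamini-Hochberg adjustment of their p-value over the listed pairs (largest gap 2.05e-15). The list starts at a mean abundance of -0.01 (log2), so it holds the more abundant pairs only, and its totals are not the full depth of the libraries, which is not given in the sources used here. Raw reads were not used here.

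The counts were fitted with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM scaling, glmQLFit and glmQLFTest, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The filter filterByExpr removed 0 pairs, the smallest total count of a pair being 868. TMM factors were 0.966 and 0.944 for the control libraries and 1.05 and 1.04 for the knockdown libraries. Contacts within a bin took 84.9% of the counts of each control library and 83.8% of each knockdown library. The common dispersion was 0.00812, a coefficient of variation of 9.01%. A chi-square statistic per degree of freedom of 8.86 between the control libraries and 4.80 between the knockdown libraries shows spread beyond counting error. Levels are CPM from edgeR with TMM-scaled library sizes, given as mean ± SD of 2 libraries. Fold changes are knockdown over control.

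Counts were simulated at the common dispersion for every pair, with no gradient between libraries. On these the test recovered 99% of 100 changes of log2 size 1 and 32% of those of size 0.5, with 4 false calls among 89239 pairs. DESeq2 recovered 97% and 27%, with 2 false calls. Differences in spread among pairs and gradients between libraries were not simulated, so false calls from them are not covered.

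Before the data were examined, the tests, the gene lists, the rule for named items and most alternatives were fixed. The rule took the 10 largest increases and the 10 largest decreases among pairs past the threshold whose libraries all moved the same way, adjoining pairs of one direction counting as 1 region with up to 3 genes named, and up to 6 genes per list by size of change, with TARDBP in addition. One of the regions is given by 2 of its genes alone, and some items that the rule named are not reported here. Genes given only as members that did not pass, with UNC13A, TET1, HOXA, HOXD and the bins of the protocadherin locus, fall outside the rule and were chosen after their values were seen.

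Gene bodies came from the RefSeq annotation of GRCh38.p14, limited to protein-coding genes on placed chromosomes. The 13 lists held 297 genes, of which 286 overlap a listed pair. They were TDP-43 cryptic exon and splicing targets, noradrenergic and mesenchymal neuroblastoma identity, R-loop processing and genome stability, DNA methylation and hydroxymethylation, genome architecture, transposable element silencing, ALS and FTD genes, long synaptic and adhesion genes, glutamate and GABA receptors, protocadherin clusters, HOX clusters and interferon response. A gene counted as differing when its body overlapped a differing pair, and each list was compared with all other tested genes by Fisher's exact test, two-sided, adjusted over the lists. A count "adjusted over the list alone" used p-values adjusted over the pairs of that list. Gene density was tested with 1000 circular shifts of the calls along each chromosome. On simulated calls with a link to gene density, that test passed in 100% of 10 runs, and without a link in 8.33% of 60. Directions were tested with an exact binomial test and chromosomes with Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

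Alternatives fixed beforehand were other thresholds, DESeq2 1.42.0 size factors and test, no filter, a replicate block, each library left out in turn, autosomes only, contacts within a bin or between bins, merged regions, genes of like length and pairs with a gene only. Those added after seeing the data were removal of the trend of the fold change with abundance by a loess fit per library, TMM within distance classes, the authors' own table, circular shifts for lists, and higher and lower pairs apart. The loess fit gave fold changes within 0.00237 (log2) of the authors' (r = 0.999997), against r = 0.925 for TMM. Compartment scores and GC content were not analysed here.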

Results

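Chromatin contacts were mapped by Micro-C, a form of chromosome conformation capture that cuts chromatin with micrococcal nuclease, in SH-SY5Y cells, an established human neuroblastoma line. There were 2 control libraries and 2 libraries of cells with a stable shRNA knockdown of TDP-43, the RNA- and DNA-binding protein encoded by TARDBP. The study as a whole concerned lasting loss of TDP-43 and its effects on R-loops, 5-hydroxymethylcytosine, transposable elements and transcription, and this comparison asked which contacts differed when TDP-43 was depleted. Counts were given for 89239 pairs of 50 kb bins of hg38, of which 48992 (54.9%) were contacts within a single bin. Over the listed pairs the control libraries held 158400914 and 163147992 contacts and the knockdown libraries 115168160 and 142424414. The median count per pair was 622 and 616 in the control libraries and 510 and 624 in the knockdown libraries. Across pairs, log2 contact levels correlated with r = 0.988 between the control libraries, r = 0.991 between the knockdown libraries and r = 0.981 to 0.984 between the groups (bin pairs are not independent replicates). The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries.

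TARDBP, the targeted gene (chromosome 1, 11012654 to 11030528), lies within 1 bin, and contacts within that bin were lower in the knockdown, at 32.9 ± 0.0424 CPM (contacts scaled to library size; ± SD, n = 2) against 38.2 ± 1.43 in control. The log2 fold change was -0.22 (SE 0.06, adjusted p = 0.00265, edgeR). None of the other 5 listed pairs that include this bin passed, with log2 fold changes from -0.45 to -0.08. The TARDBP call was lost without knockdown library 1 (adjusted p = 0.12), without knockdown library 2 (adjusted p = 0.0995) and with the trend of the fold change with abundance removed (log2 fold change -0.08, adjusted p = 0.326). An shRNA acts on the RNA, so a contact map gives no check of the knockdown itself.

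The largest increase lay at the edge of the heterochromatin of chromosome 16. Contacts within the bin at 46350001 to 46400000 rose from 0.479 ± 0.136 to 3.03 ± 0.0749 CPM (SD, n = 2 per group), a log2 fold change of 2.66 (SE 0.24, adjusted p = 4.63e-18). Contacts between that bin and the bin at 34550001 to 34600000, on the other side of the centromere, rose from 0.733 ± 0.128 to 3.72 ± 0.535 CPM (log2 fold change 2.35, SE 0.22, adjusted p = 8.16e-18). Neither bin holds a protein-coding gene, and the third-ranked increase lay in an unplaced contig (log2 fold change 1.73). A bin of the imprinted domain of chromosome 14 carries the noncoding MEG8 and the SNORD114 small nucleolar RNA genes. Its log2 fold change was 1.19, on few counts (104 and 186 in the control libraries, 280 and 298 in the knockdown libraries). The pair joining SCUBE2 and NRIP3 to DENND5A had a log2 fold change of 1.12. Contacts rose by 1.09 within RORA, which encodes a retinoid-related orphan nuclear receptor, by 1.08 within LRMDA and by 1.07 at ORC3, a subunit of the origin recognition complex, and its neighbour RARS2.

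The largest decrease was on the long arm of chromosome 8, between a bin at 141700001 to 141750000 and the bin of ADGRB1, which encodes a brain adhesion G-protein-coupled receptor. These contacts fell from 2.63 ± 0.0792 to 1.10 ± 0.197 CPM (log2 fold change -1.25, SE 0.22, adjusted p = 2.71e-06). A further region joined ADGRB1 to JRK and PSCA (log2 fold change -1.13). Beside the centromere of chromosome 12, adjacent bins at 34350001 to 34450000 fell from 4.57 ± 0.171 to 2.04 ± 0.0233 CPM (log2 fold change -1.16, SE 0.17, adjusted p = 5.47e-09). Contacts of UNKL with CRAMP1 and JPT2 had a log2 fold change of -1.10, and those of MAD1L1, a spindle checkpoint gene, with INTS1 and TMEM184A one of -1.06. Contacts of CDC25B, a cell cycle phosphatase, and HSPA12B with SMOX had one of -1.05, those within CDH4, a cadherin, one of -0.96, and those of INPP5A and NKX6-2 with CFAP46 one of -0.94. The 2 remaining regions lost their calls without knockdown library 1. SLCO4A1 with BHLHE23 went from -1.05 to -0.80 (adjusted p = 0.087), and the region of C16orf74 and EMC8 went from -0.94 to -0.66 (adjusted p = 0.208). The other 18 of the 20 named regions kept their calls under every alternative that included them. Apart from the one on chromosome 12, the regions of decrease named here lie within 5 Mb of a chromosome end. Lower pairs were common there in general, at 29.6% of all pairs against 7.53% elsewhere, so these decreases are not particular to the genes named.

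**Figure D1:**
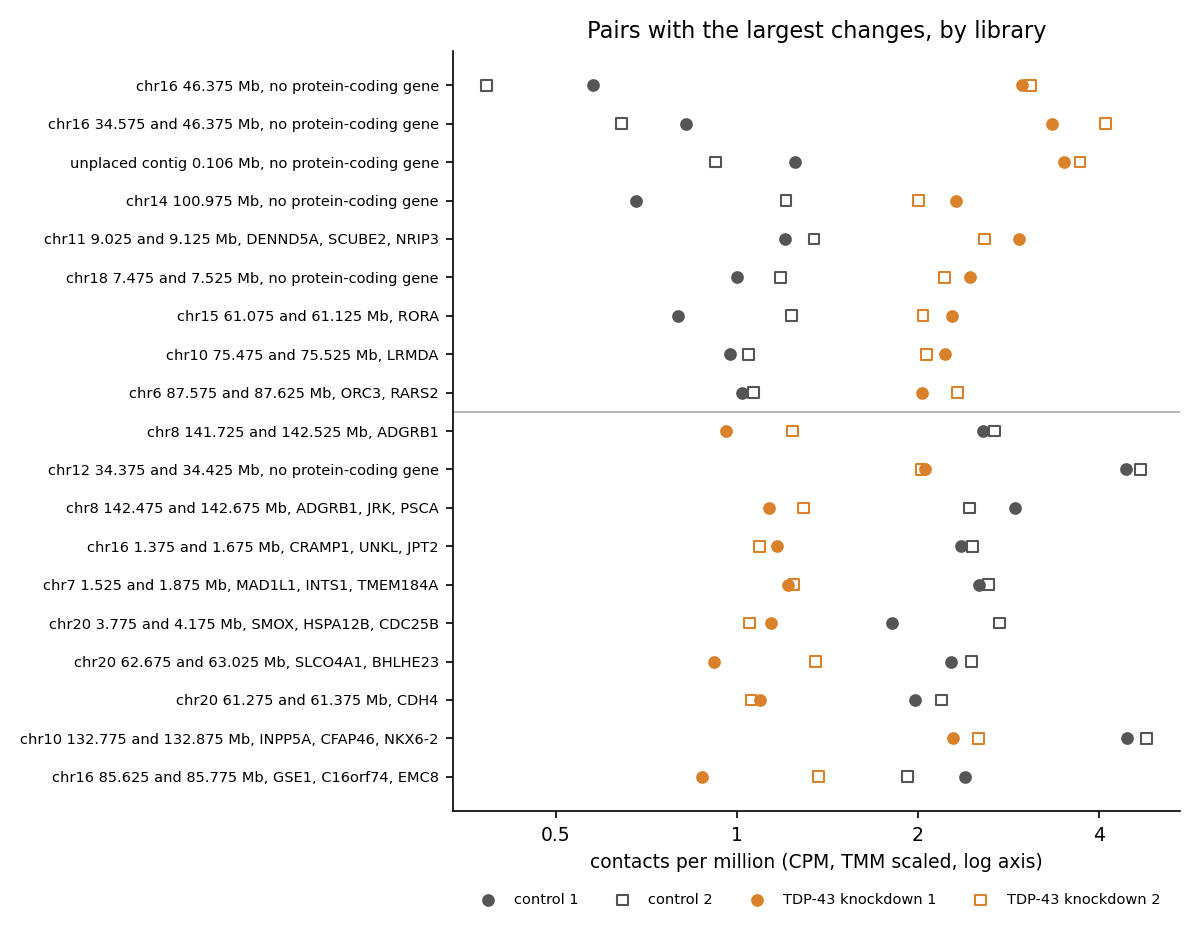
Contacts in CPM (log axis, TMM scaled) in each library for 9 of the 10 pairs with the largest increases (upper set) and the 10 with the largest decreases (lower set), labelled with chromosome, bin middle in Mb and protein-coding genes; each symbol is a library, with no error bars. Contacts within the chromosome 16 bin went from a mean of 0.479 to 3.03, and those of ADGRB1 from 2.63 to 1.10.

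Among the pairs that passed the test, more were lower than higher in the knockdown. Of the 89239 pairs, 14469 (16.2%) differed, 5138 of them higher and 9331 lower. Most changes were modest, with a median absolute log2 fold change of 0.36. The size exceeded 0.5 in 3422 pairs and 1 in 26. Genes were touched widely: of 18703 protein-coding genes that overlap a listed pair, 10743 (57.4%) overlapped a differing pair, 2201 only higher ones, 7780 only lower ones and 762 both. Over all pairs the median log2 fold change was 0.02, and over 10 equal classes of abundance it went from 0.11 in the least abundant pairs to -0.21 in the most abundant. In 56.1% of all pairs the libraries of the groups did not overlap, against 33.3% by chance. The share higher was 35.5% (exact binomial p = 6.47e-270, a description, since pairs are not independent), 23.9% with DESeq2's size factors and test together, 45.3% with the abundance trend removed, 45.7% in the authors' own table and 52.7% once adjoining pairs were merged into regions. Without knockdown library 1 or 2 the count was 4910 or 6373 and the share higher 17.9% or 21.4%. Without control library 1 or 2 it was 16764 or 13991, and 7385 pairs passed in the same direction both with TMM scaling and with the trend removed.

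More long-range pairs were lower than higher in the knockdown with TMM scaling and with the trend removed. Their share of the unscaled contacts was not lower. Pairs 200 kb or more apart took 2.20% and 2.22% of them in the control libraries and 2.22% and 2.24% in the knockdown libraries. Among the 8704 pairs 200 kb or more apart, 689 fell and 98 rose, and among the 905 pairs 500 kb or more apart, 112 fell and 5 rose. With the trend removed, 995 fell and 33 rose at 200 kb or more. Of 48992 contacts within a bin, 6982 were lower and 3625 higher (21.7% in all), and their share and direction depended on the scaling. With the trend removed 6373 of them differed, a smaller share than the 17.7% of pairs 500 kb or more apart. Of the differing ones within a bin, 34.2% were higher with TMM and 60.5% with the trend removed. At 50 to 150 kb, 1659 of 31537 pairs fell and 1415 rose (46.0% higher), against 22.6% higher with the trend removed. Scaling each distance class by itself, which centres each class by construction, gave 50.4% higher at 200 kb or more. Without control library 2 the share higher at 200 kb or more was 23.8%, against 12.5% with all libraries, and without knockdown library 2 it was 7.94%.

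**Figure D2:**
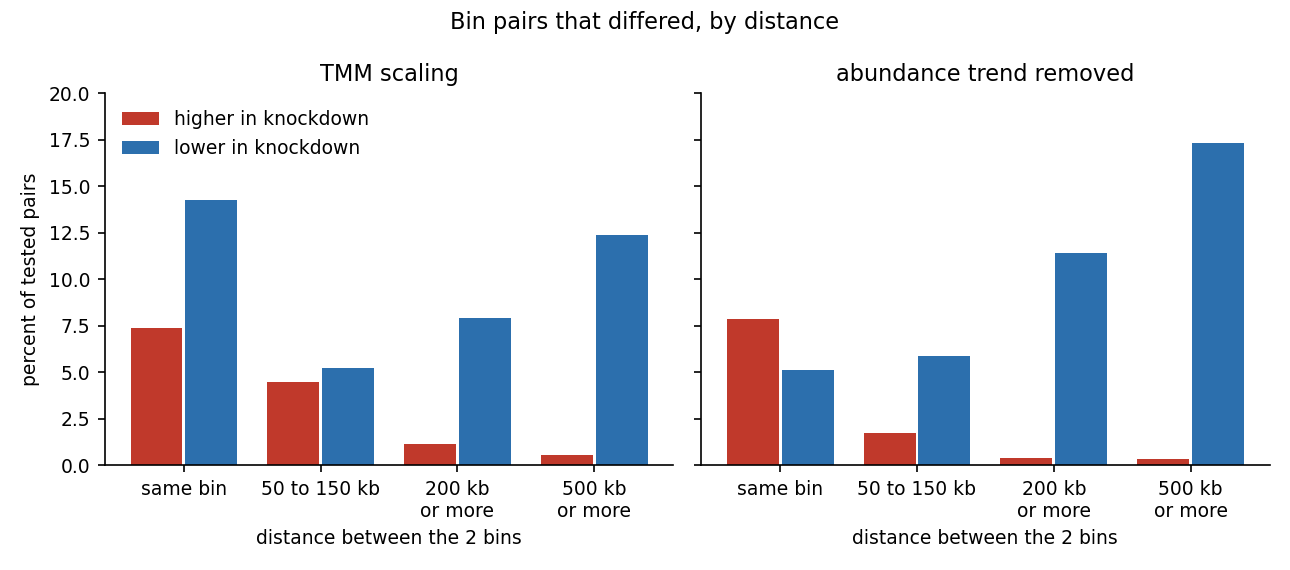
Percent of tested bin pairs that were higher (red) or lower (blue) in the knockdown at adjusted p under 0.05, by distance between the bins, with TMM scaling (left panel) and with the abundance trend removed (right panel). At 500 kb or more 12.4% and 17.3% were lower, while the balance within a bin flips from 14.3% lower and 7.40% higher to 5.14% lower and 7.87% higher.

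Pairs with lower contacts held more genes than other pairs, and pairs with higher contacts held fewer. Pairs lower in the knockdown held a mean of 2.04 protein-coding genes against 1.51 in all other pairs, and pairs higher in the knockdown held 0.873 against 1.60. Each difference gave p = 0.001 in a two-sided circular shift permutation test along the chromosomes, the smallest that 1000 shifts can give. Genes over either bin were counted, so a pair of 2 bins covers more sequence than a contact within a bin. The shifts do not hold distance fixed, so these differences also reflect the distances of the called pairs. Within single bins the differences were 0.896 for lower and -0.281 for higher pairs (permutation p = 0.001 each). With both directions together, over all pairs, the means were 1.62 and 1.55 and no difference was detected (permutation p = 0.417). That combined test passed without control library 2 (difference 0.0272, permutation p = 0.02) and without knockdown library 2 (0.267, permutation p = 0.029), within single bins (0.532, p = 0.001) and with gene-bearing pairs alone (-0.0294, p = 0.003). The shifts are not centred on 0 (most lay between 0.0381 and 0.173 for all pairs and libraries), so a pass alone does not say that differing pairs held more genes. Among contacts within gene-free bins 5.32% were lower and 9.07% higher, while within bins of 6 or more genes 86.0% were lower and none was higher. With the trend removed those bins gave 25.4% lower and 9.65% higher, and gene-free bins 3.04% lower and 7.56% higher. The deficit of genes in higher pairs within single bins then shrank from -0.281 to -0.0374 (permutation p = 0.002). In simulations with no link between calls and genes, 8.33% of 60 runs gave p under 0.05, so p-values near that threshold carry little weight.

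**Figure D3:**
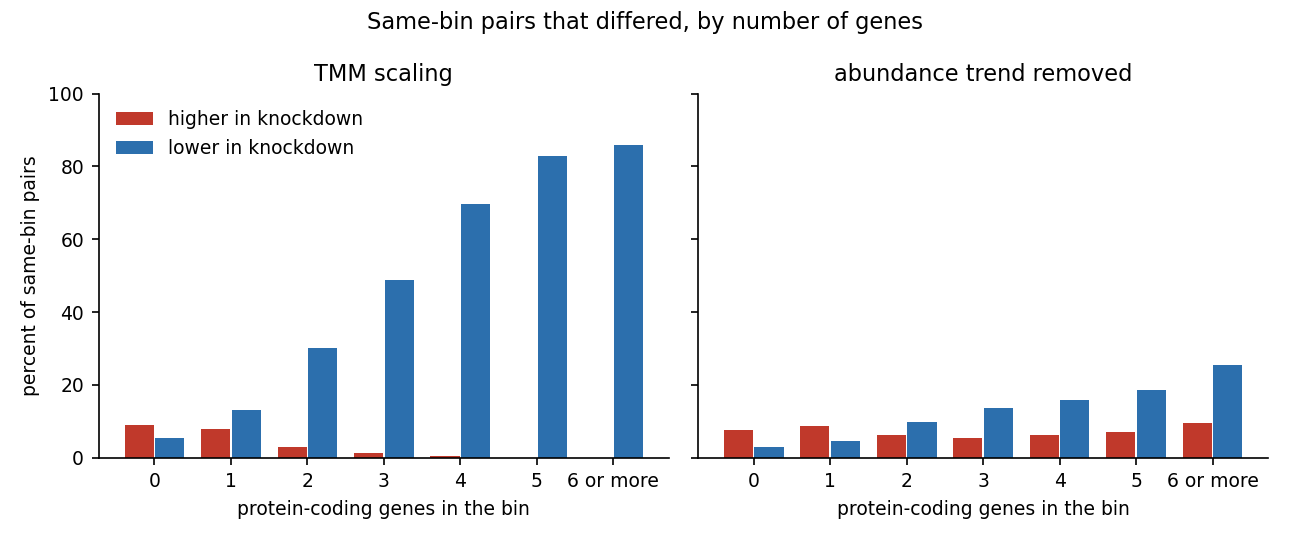
Percent of same-bin pairs higher (red) or lower (blue) in the knockdown at adjusted p under 0.05, by the number of protein-coding genes that overlap the bin, with TMM scaling (left panel) and with the abundance trend removed (right panel). The lower share goes from 5.32% in gene-free bins to 86.0% in bins of 6 or more genes with TMM, and from 3.04% to 25.4% with the trend removed.

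With TMM scaling, most genes of the noradrenergic identity of neuroblastoma overlapped lower contacts. Of 19 tested, 17 overlapped a differing pair (17 adjusted over the list alone), 13 only lower, 1 only higher and 3 both. Once the trend was removed, 8 had a lower pair, 7 of them only lower ones, and the list did not exceed other genes in lower pairs (adjusted p = 0.365). Contacts between the bin of TH, the rate-limiting enzyme of catecholamine synthesis, and a bin 300 kb away fell from 2.83 ± 0.336 to 1.51 ± 0.0279 CPM (SD, n = 2 per group; log2 fold change -0.91, SE 0.21, adjusted p = 0.000371). Contacts within a bin of RET, a receptor tyrosine kinase of neural crest lineages, fell from 99.8 ± 6.36 to 68.8 ± 0.764 CPM (log2 fold change -0.54, SE 0.06, adjusted p = 1.86e-15; -0.22 with the trend removed). The list exceeded all other genes (Fisher's exact test, two-sided, adjusted p = 0.0278; circular shifts, adjusted p = 0.0325). The call was lost against genes of like length (adjusted p = 0.0538), with the trend removed (0.0811) and in the authors' table (0.082). By the same Fisher's exact test it was lost with DESeq2 (0.136), with the replicate block (0.0547), with TMM within distance classes (0.0719) and at the 0.01 threshold for pairs (0.131). It was lost without control library 1 or 2 but kept without knockdown library 1 or 2, each such fit leaving 1 library in a group. Of 20 mesenchymal identity genes, 12 overlapped a differing pair (12 adjusted over the list alone; adjusted p = 1), 9 only lower, and within a bin at NOTCH3, which encodes a Notch receptor, contacts fell from 79.3 ± 0.513 to 57.8 ± 1.71 CPM (log2 fold change -0.46, or -0.18 with the trend removed).

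The clusters of developmental and adhesion genes were also mostly lower where they differed, as were genes at large (7780 of 10743 only lower). Of 22 HOX genes, which pattern the body axis, 20 overlapped a differing pair (20 adjusted over the list alone), 14 only lower, 2 only higher and 4 both (Fisher's exact test, adjusted p = 0.0119). HOXA10 and HOXA13 shared a pair with a log2 fold change of -0.53 (-0.61 with the trend removed). For HOXD8 and HOXD10 it was -0.34, but 0.01 and not past the threshold with the trend removed (adjusted p = 0.89), while HOXB13 had a higher pair (log2 fold change 0.70). Neighbouring HOX genes share bins and are not independent, and with circular shifts the call was lost (adjusted p = 0.477), as it was with the trend removed (0.0563; 0.0409 for lower pairs alone, but 0.126 against genes of like length). Of 16 clustered protocadherin genes, which encode neuronal cell-surface recognition proteins, 11 overlapped a differing pair and every one of these was lower (11 adjusted over the list alone; adjusted p = 0.841). For lower pairs alone with the trend removed, the list passed against all other genes (adjusted p = 0.00889) and genes of like length (0.0153). These tests count genes that share bins as independent. With circular shifts and TMM the list did not pass, both directions together (adjusted p = 0.856). The wider family of cadherins and clustered protocadherins gave an adjusted p of 0.13 by circular shifts, for lower pairs with the trend removed. PCDHA1, PCDHA2, PCDHA4 and PCDHA6 share the bin at 140800001 to 140850000 of chromosome 5, where contacts fell from 9.76 ± 0.62 to 5.60 ± 0.458 CPM (SD, n = 2 per group; log2 fold change -0.80, SE 0.11, adjusted p = 3.66e-10). Over the 22 bins of the locus and its flanks, drawn after their values were seen, 10 were lower and 0 higher, and 8 were lower with the trend removed. The lower bins at 140.625, 141.625 and 141.675 Mb lie in the flanks, hold no protocadherin gene and did not pass with the trend removed.

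**Figure D4:**
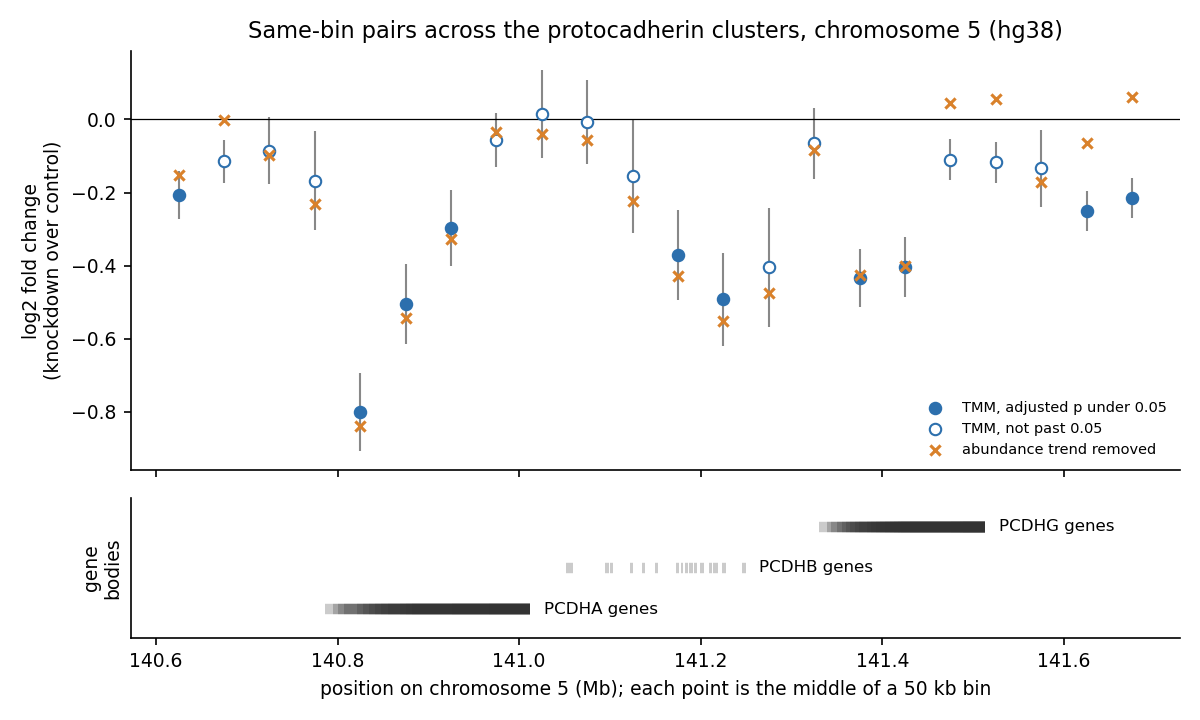
Log2 fold change of contacts within each 50 kb bin across the protocadherin clusters of chromosome 5 (position in Mb, hg38), with TMM scaling (circles, filled at adjusted p under 0.05, bars show the standard error of the fit) and with the abundance trend removed (crosses), above the gene bodies. The lowest bin stands at -0.80 with TMM and -0.84 with the trend removed. The bins at 141.475, 141.525 and, in the flank, 141.675 Mb go from negative with TMM to positive with the trend removed.

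Genes whose splicing depends on TDP-43 were mostly at lower contacts where they differed, as were genes at large (7780 of 10743 only lower). Of 26 such targets, 19 overlapped a differing pair (20 adjusted over the list alone), 16 only lower and 3 only higher. Contacts between a bin of AGRN, which encodes the synapse organiser agrin, and a bin 150 kb away fell from 4.08 ± 0.261 to 2.17 ± 0.331 CPM (SD, n = 2 per group; log2 fold change -0.91, SE 0.17, adjusted p = 1.09e-05). STMN2, a target with a well-known cryptic exon, overlapped no differing pair, and UNC13A had a lower pair (log2 fold change -0.19) that did not pass with the trend removed. With TMM the list did not exceed other genes (Fisher's exact test, adjusted p = 0.302) or genes of like length (adjusted p = 0.365). Nor did it pass with circular shifts, run for lists with TMM alone (19.8 genes expected, adjusted p = 0.856). By Fisher's exact test it passed with the trend removed (0.00454) and in the authors' table (0.0229). These 2 are nearly the same fit and do not count as separate support. It also passed without knockdown library 1 or 2, fits that leave 1 library in that group. Of 29 ALS and FTD genes, 16 overlapped a differing pair (16 adjusted over the list alone; adjusted p = 1), and contacts of TUBA4A, a tubulin gene, fell from 3.18 ± 0.14 to 1.84 ± 0.0152 CPM (log2 fold change -0.79, SE 0.19, adjusted p = 0.00102).

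Of 42 long synaptic and adhesion genes, 25 overlapped a differing pair (23 adjusted over the list alone), 9 only higher, 6 only lower and 10 both. Contacts within a bin of FHIT, a gene at a common fragile site, rose from 1.88 ± 0.295 to 3.53 ± 0.248 CPM (SD, n = 2 per group; log2 fold change 0.91, SE 0.19, adjusted p = 5.46e-05). Those within a bin of LSAMP, a limbic adhesion protein gene, rose from 1.60 ± 0.135 to 3.01 ± 0.22 CPM (log2 fold change 0.91, SE 0.20, adjusted p = 0.000218). In either direction the list did not differ from other genes (adjusted p = 1), and with circular shifts fewer of its genes were touched than the 35.7 expected (adjusted p = 0.013). Its 19 genes with higher pairs exceeded other genes (adjusted p = 0.00017), but not genes of like length (adjusted p = 0.965). Of 17 glutamate and GABA receptor genes, 11 overlapped a differing pair (11 adjusted over the list alone; adjusted p = 1), 7 only higher, 2 only lower and 2 both. Their 9 genes with higher pairs exceeded other genes (adjusted p = 0.00544), but not genes of like length (adjusted p = 0.668).

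Among genes that act on chromatin and nucleic acids, no list differed from other genes with both directions together. Of 22 R-loop and genome stability genes, 8 overlapped a differing pair (8 adjusted over the list alone; adjusted p = 0.219), and contacts between the bin of DDX5, an RNA helicase gene, and the next bin rose from 3.50 ± 0.671 to 5.45 ± 0.167 CPM (log2 fold change 0.64, SE 0.14, adjusted p = 0.000251). Of 13 DNA methylation and hydroxymethylation genes, 10 did so (10 adjusted over the list alone; adjusted p = 0.378), 8 only lower, DNMT1 and DNMT3A among them, while TET1 had only a higher pair that was lost with the trend removed (adjusted p = 0.0776). Of 22 genome architecture genes, 13 did so (12 adjusted over the list alone; adjusted p = 1), 11 only lower. Contacts fell by 0.53 on the log2 scale within a bin of LMNB2, which encodes a B-type lamin, and by 0.33 within a bin of LBR, the lamin B receptor. With the trend removed these were -0.23 and -0.13, both still past the threshold. Of 18 genes that silence transposable elements, 10 did so (9 adjusted over the list alone; adjusted p = 1). Contacts fell by 0.48 within a bin of EHMT1, a histone methyltransferase gene (-0.29 with the trend removed), and by 0.46 within a bin of ATF7IP, a partner of SETDB1. Of 20 interferon response genes, 7 did so (7 adjusted over the list alone; adjusted p = 0.219), 4 only higher and 3 only lower. Those 3 were fewer than among other genes (adjusted p = 0.0312), though not with circular shifts (adjusted p = 0.603). Over all lists, 17 of 77 named genes kept the call of their pair under every alternative, and 47 lost it without knockdown library 1, 39 without knockdown library 2, 23 without control library 1 and 12 without control library 2.

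With TMM scaling, chromosomes 22, 19, 16 and 17 differed most, in 23.7%, 23.3%, 23.2% and 20.6% of their pairs, and chromosome 13 least, in 11.7%. With the trend removed the shares were 14.7%, 11.8%, 16.2% and 15.4%, and chromosome 19 no longer differed from the others (adjusted p = 0.203). Of the differing pairs on chromosome 19, 11.8% were higher, against 67.9% on chromosome X. Of 23 chromosomes, 14 differed from the others (Fisher's exact test, two-sided, adjusted p under 0.05). Neighbouring pairs are not independent, so this count is a description. With adjoining pairs merged into regions only 2 did, chromosomes 4 and 15. That test set merged regions against uncalled pairs that were not merged, which lowers the share most where called pairs adjoin. SH-SY5Y is aneuploid, and copy number was not analysed here.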

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

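The removal of the abundance trend, TMM within distance classes, the authors' own table, circular shifts for lists, separate directions for lists and gene density, the classes of 200 kb and 500 kb or more, and the restriction to contacts within a bin for gene density and replicate agreement were chosen after the data were seen; the rest were planned. The number of differing pairs, 14469, was 8738 at an adjusted p of 0.01, 2510 with pairs 50 kb or more apart alone and 7086 as merged regions, and 4910 to 16764 with a library left out, a lone library being assumed to vary like the other group. The share higher was 52.7% as merged regions, where the lower pairs adjoin more often (9331 pairs made 3349 regions, and 5138 higher pairs made 3737). Within a bin it turned from 34.2% to 60.5% with the trend removed and 61.0% in the authors' table. At 200 kb or more it was 50.4% with TMM within distance classes, which centres each class by construction. The chromosomes that differed numbered 2 as merged regions, and the cause was not tested. The lists past the threshold, 2 in all, numbered 1 (HOX) at 0.01, with genes of like length, with the replicate block, with DESeq2 and within distance classes. With both directions together they numbered 1 with the trend removed and in the authors' table, the TDP-43 targets, neither of the lists past with TMM. With circular shifts they were the noradrenergic and the long synaptic genes. They numbered 5 with directions apart and 1 to 4 with a library left out. The cause was not tested. The gene difference of all differing pairs, 0.0745, was -0.0294 with gene-bearing pairs alone, 0.532 within a bin and 0.0272 to 0.267 with a library left out. For lower and for higher pairs apart it was 0.267 to 0.896 and -0.814 to -0.281 over the thresholds, fits, left-out libraries and subsets named here, each past the threshold. With a subset and a scaling changed together, higher pairs within a bin with the trend removed gave -0.0374 (permutation p = 0.002). Lower pairs within 5 Mb of a chromosome end gave 0.0863 (permutation p = 0.779). Replicate agreement within groups, 0.990, was 0.994 within a bin. At TARDBP the log2 fold change was -0.25 to -0.19 with a library left out, and -0.0809 with the trend removed and -0.0808 in the authors' table, no longer past the threshold. Of the 77 named genes, 23 lost their call with the trend removed, 20 with DESeq2 and 6 within distance classes, and of the 20 named regions none did. The same-number libraries of the groups showed no shared deviation (r = 0.0192), and the block gave 15663 pairs, 14442 of them shared. The filter removed 0 pairs, so no filter gave the same result and tests nothing. The planned restriction to contacts at or below 20 kb was run as pairs within a bin, since bins of 50 kb cannot separate them, and short contacts across a bin border are not among these. The start-site alternative for lists was not run, as the gene table gives no strand, nor were compartment switches with their alternatives, or quantile normalization, as the table holds counts. Of simulated changes of log2 size 0.5, 32% were recovered at the depth and common dispersion of these libraries, which were not varied apart.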

Other observations

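The families, loci and chromosome ends described here were chosen after the values were seen, as were the tests of the chromosome ends against the abundance trend, of gene density against the replicate libraries, the abundance trend, contact distance and position near ends, of unmappable sequence at chromosome 16, and of other splits of the libraries; the rest were written down before their results.

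Contacts near the ends of chromosomes were lower in the knockdown. Within 5 Mb of an end, 29.6% of 11793 pairs were lower and 0.941% higher, against 7.53% and 6.49% of 77374 pairs elsewhere. Within single bins the median log2 fold change was -0.30 in the first Mb, -0.32 in the second Mb, -0.16 from 2 to 5 Mb, -0.02 from 5 to 10 Mb and 0.05 beyond 40 Mb. With the trend removed the first 4 of these were -0.13, -0.12, -0.05 and 0.02. Distance from an end was measured from the first or last listed bin, and a start was left out where that bin lies at 5 Mb or more. Of the 41 ends used, 37 had a lower median than the rest of their chromosome, and 40 did with the abundance trend removed. Most bins of a stretch of 8q that includes ADGRB1 were lower, 31 of 32 (24 with the trend removed).

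Single loci stood out as well. In the imprinted domain of chromosome 14, 11 of 12 bins around DLK1 and RTL1 were lower (7 with the trend removed). The remaining bin, with MEG8 and the SNORD114 genes, was higher (1.19), but it held few contacts. Its control level (geometric mean) was 0.906 CPM, against 20.0 and 46.0 in the adjoining bins. The 2 control libraries differed there (0.680 and 1.21 CPM). Whether the bin is mostly unmappable was not tested. Beside the centromere of chromosome 12, contacts within the bins at 34300001, 34350001 and 34400001 had log2 fold changes of -0.79, -0.91 and -0.93 (-0.46, -0.59 and -0.98 with the trend removed). Of 71 pairs that touch unplaced or alternate contigs, 19 differed, 17 of them lower. Among 10 gene families, solute carrier genes overlapped higher pairs less often than circular shifts gave (68 of 378 genes, 95.8 expected, adjusted p = 0.04; trend removed, adjusted p = 0.02). Their share, 18.0%, was nonetheless above the 15.8% of all genes. Zinc finger genes did so with the trend removed (27 of 505 genes, 66.9 expected, adjusted p = 0.02) but not with TMM (39 genes, adjusted p = 0.0599). No test passed for olfactory receptors, cluster histones, keratin-associated proteins, potassium channels, cadherins, collagens, HLA or HOX genes.

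For the lower contacts near chromosome ends, gene density alone is argued against, since the lower share was higher near an end at every gene number, by at least 29.4 percentage points (at least 15.8 with the trend removed). The abundance trend as the whole cause is argued against too, since 21.3 points remained with it removed (permutation p = 0.001, the smallest that 1000 shifts can give). Between the control libraries the median also stepped near ends, by 0.07, against -0.25 between the groups, a ratio of 0.276. A gradient between library preparations therefore cannot be told apart from the knockdown, as the ratio lies between the bounds set beforehand, and GC content was not analysed here. An effect of TDP-43 loss on contacts near chromosome ends is a candidate explanation that these libraries leave untested.

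For the lower contacts in gene-rich bins, the excess of genes in lower pairs was 0.862 with the abundance trend removed, 0.896 within single bins and, more than 5 Mb from an end, 0.644 over 2454 lower pairs with the trend removed. Of these, 0.862 and 0.644 pool contacts within a bin with pairs of 2 bins, which count genes over both. Within single bins with the trend removed the excess was 0.553, and 0.403 more than 5 Mb from an end. Each had a permutation p = 0.001. This argues against abundance, distance or position within 5 Mb of an end, each alone, as the whole cause of that excess. The gradient from the ends goes further and is not covered. With the trend removed, 5.66% of contacts within a bin were lower at 5 to 10 Mb, against 2.72% beyond 40 Mb. Within 5 Mb of an end, where 3485 lower pairs lie, no excess was detected with TMM (0.0863, permutation p = 0.779), while it was 0.571 with the trend removed (p = 0.002). An excess among called pairs does not say that gene-rich bins were lower on balance. More than 5 Mb from an end with the trend removed, 6.75% of bins of 3 or more genes were lower and 7.39% higher. Their median log2 fold change was 0.000591. Gene-free bins there gave 1.97% and 7.93%, and bins of 3 or more genes near an end 52.4% and 0%. With TMM the step from gene-free bins to bins of 3 or more genes was -0.30 between the groups and 0.10 between the control libraries, a ratio of 0.33. With the trend removed the step was smaller. The median log2 fold change went from 0.0521 in gene-free bins to -0.0190 in bins of 3 genes and -0.0338 in bins of 6 or more. A difference between library preparations, for example in nuclease digestion of open chromatin, could contribute and cannot be told apart from an effect of the knockdown, and GC content is open.

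For the rise at the chromosome 16 heterochromatin edge, a copy number gain that reaches into the neighbouring 1 Mb is argued against. The median log2 fold change of the other 19 same-bin pairs within 1 Mb was -0.14 (-0.135 unrounded). All of these lie on the side away from the centromere, so a gain confined to the heterochromatin cannot be judged from them. The control count of the bin was 6.52% of the median same-bin count, which is consistent with a mostly unmappable bin that holds reads of repeat copies. Whether the repeats changed in contact, in copy number or in mapping was not tested.

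The median log2 fold change did not fall steadily with distance (0.02 within a bin, 0.06 at 50 to 150 kb and -0.12 at 200 kb or more). The step from within a bin to 200 kb or more was -0.14, and the larger step between libraries of a group was 0.384 of it in size. From 50 kb to 200 kb or more the step was -0.21, and the larger step between libraries of a group 0.03. Among gene-free pairs the step was 0.773 of that over all pairs, and 0.365 to 0.857 over the 4 pairings of a knockdown with a control library. The bound set beforehand was met by the pooled value; the requirement that every pairing meet it was added after that value was seen, so the gene-dense location of distant pairs is left open. Among pairs with 3 or more genes the step was 0.05.

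Of the 3 splits of the 4 libraries into equal groups, 1, the real one, gave 14469 differing pairs, and the highest of the others gave 0 with edgeR (694 and 599 pairs at an unadjusted p under 0.05, against 25525). Each of the other splits puts a control and a knockdown library in each group. The difference between the real groups then enters the spread of that fit, so few calls are built in. The splits are also too few for a share under 0.05, and no conclusion is drawn from them.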
